A study of Mus musculus with 2 samples.

How the data were processed

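Thymocyte RNA of 3 null and of 3 wild-type mice was pooled per genotype and amplified, per the labels, which name thymocytes in the description and thymus as the source. For each array, 750 ng of labelled cRNA per dye was hybridised for 17 h to an Agilent mouse array of 60-base probes. The first array held null in Cy5 and wild type in Cy3, and the second the reverse. Scans were processed with Agilent Feature Extraction 7.1, per the submitters' processing notes. Its background and dye settings were defaults, per the series' design text, and are not detailed further in the sources used here.

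The deposited values are log ratios, taken as log10 because that is the convention of this software for its ratio; the base is not stated in the sources used here. All were converted to log2. The medians of the deposited log10 values over all features were -0.00141 on the array with null in Cy5 and 0.00112 on the array with null in Cy3, so no centring was added, and whether the submitters centred them is unknown. All 80 exact zeros of the first column are written 0, and all 82 of the second are written -0, which is what multiplying by -1 leaves. The second column was therefore read as already turned, so that both columns give null over wild type, and their mean is the genotype effect. The plan made before the data were examined had assumed raw Cy5 over Cy3 ratios in both columns, with the difference of the columns divided by 2 as the effect; that reading is reported as an alternative chosen after seeing the data. In 1030 genes with exactly 2 features, the features correlated with r = 0.326 for the mean of the arrays and 0.0386 for the difference divided by 2. Another 474 features without a gene name went at least 2-fold opposite ways on the 2 arrays. The scale and the direction are thus inferred and not stated.

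Of 22393 features, 18218 have 1 gene symbol, 16 have several and 4159 have none in the platform annotation used here. For 18175 features the symbol was updated by gene ID through a RefSeq table of assembly GRCm38.p6, and features of the same symbol were averaged, giving 16504 genes, of which 1193 have several features. The array's genome build is not given in the sources used here, so that table served for names only, and no coordinates are printed. The targeted gene and results that need it are not reported here. Features with several or no symbols entered no gene.

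With 1 pool per genotype no test across samples was possible, and no p-value was computed. Genes were called at 1.5-fold or more in the same direction on both arrays. The number of arrays limits the precision, and signal over background is unknown because the file holds no intensities. In 48 genes with 10 or more features, the median SD between features was 0.06 in log2 on each array. The largest was 0.14 with null in Cy5 and 0.43 with null in Cy3. In 45 of these genes all features come from 1 sequence record, so this SD says little about features from different records. The median of each of 26 gene lists, fixed before the data were examined, was set against 10000 random lists of the same size. The lists were nuclear receptors and clock, apoptosis, double positive, double negative, T cell receptor signalling, mature single positive and selection, replication, mitosis, G1 regulators, type 17, cytokines, chemokines and adhesion, interferon, glycolysis and hypoxia, sterol and lipid, glucocorticoid and stress, immediate early, 7 lists of markers of other cell types, sex-linked and ribosomal protein genes. Of their members, 21 are on more than 1 list.

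Genes were named by a rule fixed before the data were examined. It takes the 12 highest and 12 lowest genes, ranked by the smaller of the 2 absolute ratios, up to 4 members of each list that passed the size rule, and Bcl2l1, Cdkn1b, Rora, Cd4, Cd8a and Rag1 whatever their value. Members of gene families in the closing section were chosen after their values were seen.

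The rule was tested on simulated arrays with noise drawn from the difference of the 2 real arrays divided by 2. It recovered 71.4% of genes changed 1.75-fold, 98.6% changed 2-fold and 100% changed 3-fold, among 16504 genes, and called 130 of 16304 unchanged genes. Alternatives were centring, each array alone, the feature with the largest change, other thresholds, a limit on the dye term, the log base and the sign of the second column. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.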

Results

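Thymocytes, the developing T cells of the thymus, were compared between null mice, in which the gene studied was inactivated, and wild-type mice. The purpose stated in the labels was to find genes whose expression in thymocytes differs between the genotypes. The samples' source is labelled thymus, while their description names thymocytes. Equal amounts of RNA from 3 mice were pooled per genotype, and the same 2 pools were hybridised to 2 two-colour arrays with the dyes exchanged. The 2 arrays are therefore 1 replicate of 1 pool per genotype, the spread between mice was not measured, and no p-value was computed. A gene was called higher or lower when it changed at least 1.5-fold in the same direction on both arrays, and each SD below is the technical spread between the 2 arrays. Values are log2 of null over wild type, averaged over both arrays. This direction is likely and not stated in the file; it rests on the dye labels of the first array and on signs of negation in the second column.

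In the null pool, 68 of 16504 genes were higher and 183 were lower. The higher genes included Gzma, 3 histone H4 genes, 7 of 47 measured genes of DNA replication and 2 of 44 of mitosis. The lower genes included 13 of 44 genes of mature thymocytes and selection, 8 of 27 immediate early genes and several chemokine genes. Cd69, Egr1 and Klf2 are on both of the first lists and enter both counts. By the same size rule, 72 genes went opposite ways on the 2 arrays, 16 of them higher and 56 lower on the array with null in Cy5, a direction that dye and noise can give and a genotype effect cannot. On simulated arrays, the rule called 130 of 16304 unchanged genes, so part of the 251 calls can be noise. The simulated noise came from the difference of the arrays divided by 2, which also holds dye bias. The count of 130 is thus no estimate of the false calls among the 251. At 2-fold on both arrays, 7 genes were higher and 43 lower, against 9 that went opposite ways. Across all genes, which are not independent replicates, the arrays correlated with Pearson's r = 0.238 and Spearman's rho = 0.0792. The mean of the arrays had an SD of 0.22 over genes, and the dye term, the difference of the arrays divided by 2, had an SD of 0.18.

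**Figure D1:**
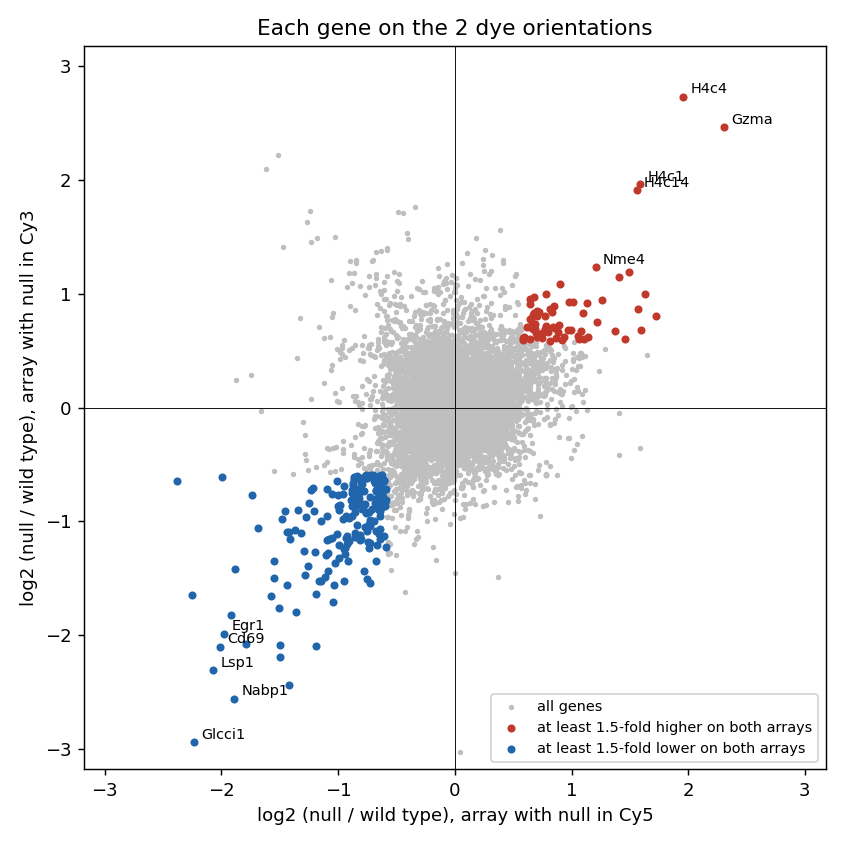
Log2 of null over wild type for each gene on the array with null in Cy5 (x axis) and on the array with null in Cy3 (y axis), with the 68 genes at least 1.5-fold higher on both arrays in red and the 183 lower in blue. Most of the 16504 genes lie around 0 on both axes, and the 72 genes that went opposite ways lie in the upper left and lower right.

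The highest gene in the null pool was Gzma, a serine protease of cytotoxic granules, at 2.38 (SD 0.11), a 5.22-fold difference. The histone genes H4c4 (2.34, SD 0.54), H4c1 (1.78, SD 0.26) and H4c14 (1.73, SD 0.25) followed. H4 genes have similar coding sequences, so their probes may bind transcripts of one another and the assignment to a copy is uncertain. The measured H4 genes did not all move together, since H4c9 stood at 0.37, H4c11 at 0.03 and H4c8 at -0.02. Nme4, a mitochondrial nucleoside diphosphate kinase, stood at 1.22 (SD 0.02). Ngp, a neutrophil granule protein, stood at 1.34 (SD 0.22), and Stra8, known from the entry of germ cells into meiosis, at 1.28 (SD 0.18). Phlda1 reached 1.31 with a wider spread between the arrays (SD 0.44). Myc, a transcription factor that drives growth, was 2.15-fold higher (1.10, SD 0.23). Dut, which removes dUTP from the nucleotide pool, was 1.96-fold higher (0.97, SD 0.06), and Ccne2, a cyclin of the G1 to S transition, was 1.94-fold higher (0.95, SD 0.04). Pgpep1l completed the 12 highest genes at 1.03 (SD 0.15).

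The lowest gene was Glcci1, a glucocorticoid-induced transcript, at -2.59 (SD 0.50), a 6.01-fold difference. Nabp1, a single-stranded DNA binding protein, stood at -2.22 (SD 0.47) and Lsp1, a leukocyte actin-binding protein, at -2.19 (SD 0.17). Cd69, an activation marker that thymocytes gain on positive selection, was 4.16-fold lower (-2.06, SD 0.06). Egr1, a transcription factor induced by T cell receptor signals, was 3.95-fold lower (-1.98, SD 0.01). The chemokine genes Ccl22 (-1.95, SD 0.43), Ccl21c (-1.94, SD 0.20) and Ccl12 (-1.63, SD 0.18) were lower, with Ccl21c uncertain because it belongs to a set of near-identical copies. Reg3g, a secreted antimicrobial lectin, stood at -1.87 (SD 0.07), and Wfdc18 at -1.84 (SD 0.49). F13a1, a coagulation factor subunit made by macrophages, stood at -1.79 (SD 0.41). Mr1, which presents antigen to mucosal-associated invariant T cells, stood at -1.62 (SD 0.05).

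**Figure D2:**
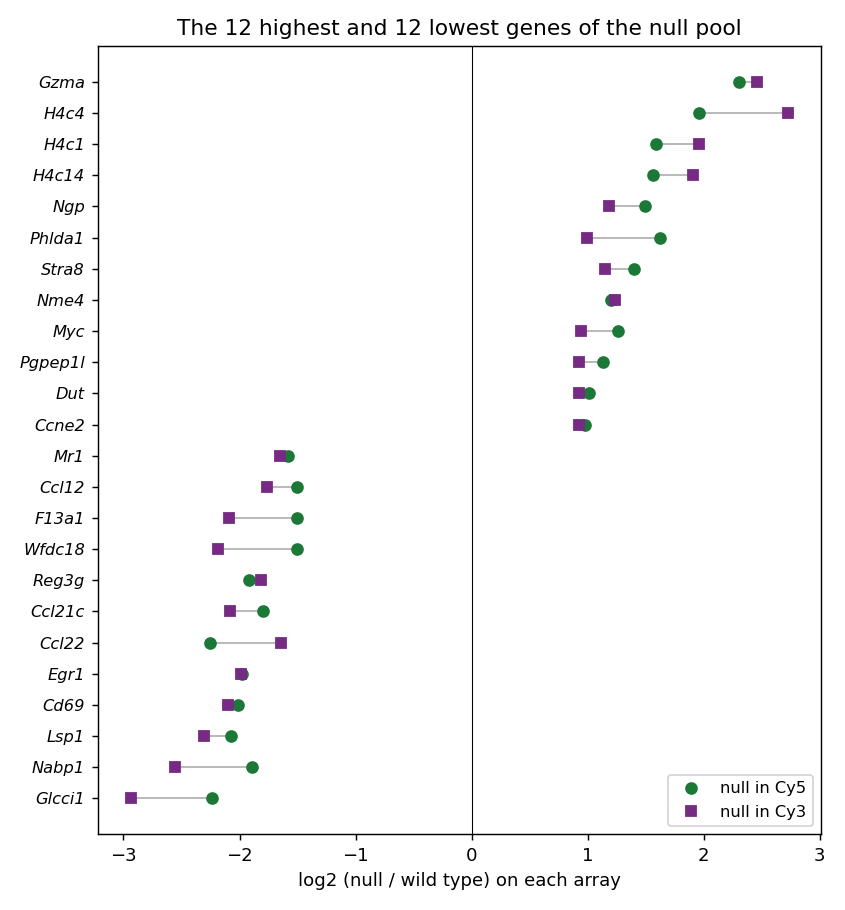
Log2 of null over wild type on the array with null in Cy5 (circles) and on the array with null in Cy3 (squares) for the 12 highest and 12 lowest genes, chosen by the smaller of their 2 absolute ratios. Gzma lies at 2.31 and 2.46, and Glcci1 at -2.24 and -2.94.

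Thymocyte gene lists fixed before the data were examined had medians below 0. Where 1 array alone moved a list's median by over 1.5 times, both arrays' medians are given below in place of their SD, the array with null in Cy5 first. Of 44 measured genes of mature single positive thymocytes and selection, 13 were lower, none was higher, and 34 lay below 0 on both arrays, with a median of -0.31 (SD 0.08). Gimap4, a GTPase of maturing lymphocytes, stood at -1.65 (SD 0.33) and Cd52, a small surface glycoprotein of mature lymphocytes, at -1.58 (SD 0.31). Of 26 genes of double positive thymocytes, 5 were lower and none higher, with a median of -0.23 (arrays -0.06 and -0.34). The 5 were Spo11 (-1.30, SD 0.37), Rag1 (-1.13, SD 0.53), Satb1 (-1.02, SD 0.10), Ccr9 (-0.96, SD 0.36) and Cd4 (-0.67, SD 0.01). Rag1 encodes a recombinase of T cell receptor genes. Of 30 T cell receptor signalling genes (median -0.23, arrays -0.27 and -0.09), Cd6 at -1.28 (SD 0.02) and Ptprc at -0.76 (SD 0.04) were lower. Of 27 double negative progenitor genes (median -0.02, arrays -0.07 and -0.02, percentile 21.0 among random lists), Il7r at -0.91 (SD 0.45) was lower. Of 27 immediate early genes (median -0.26, SD 0.02), 8 were lower, among them Ier5 at -1.10 (SD 0.06), and Myc alone was higher. Of these 8, Cd69, Egr1 and Klf2 are also among the 13 lower genes of the mature and selection list.

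The replication and mitosis lists had medians above 0, though few of their members passed the rule. Of 47 DNA replication and S phase genes, 44 lay above 0 on both arrays and 7 passed the rule, none of them lower, with a median of 0.58 (SD 0.07). Mcm6 and Mcm3, subunits of the replicative helicase, stood at 0.87 (SD 0.03) and 0.75 (SD 0.04). Of 44 mitosis genes, 39 lay above 0 on both arrays and 2 passed the rule, with a median of 0.40 (SD 0.09). These were Bub1, a spindle checkpoint kinase, at 0.88 (SD 0.37), and Cks1b, a subunit of cyclin-dependent kinases, at 0.78 (SD 0.09). Of 26 G1 regulators and inhibitors of cyclin-dependent kinases (median -0.01, arrays 0.0039 and 0.06, percentile 29.7), Myc was higher, and Btg1, an antiproliferative gene, was lower at -1.50 (SD 0.09). Cdkn1b, an inhibitor of cyclin-dependent kinases, did not pass the rule (-0.35, SD 0.24). The 34 ribosomal protein genes had a median of 0.43, with 0.63 on the array with null in Cy5 and 0.28 on the other, and none passed the rule. The 25 sterol and lipid metabolism genes had a median of 0.31, with array medians of 0.25 and 0.18, both below it, and none passed the rule.

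Survival and cytokine genes gave smaller values. Of 29 apoptosis regulators (median -0.09, arrays -0.21 and -0.06), Bcl2a1b at -1.12 (SD 0.06), one of several near-identical copies, and the death receptor gene Fas at -0.75 (SD 0.15) were lower. Bcl2l1, which encodes the survival protein Bcl-xL, did not pass the rule at -0.18 (SD 0.04). Of 21 genes of the type 17 programme (median -0.07, percentile 1.37), Ltb at -1.30 (SD 0.98) and Ccl20 at -1.26 (SD 0.25) were lower. Of 39 cytokine and receptor genes (median -0.10, arrays -0.20 and -0.04), Ifngr1 (-1.11, SD 0.46), Il7r, Cish (-0.68, SD 0.12) and Jak1 (-0.67, SD 0.02) were lower. Of 34 chemokine, receptor and adhesion genes (median -0.15, SD 0.01), 6 were lower, among them Cxcl10 at -1.38 (SD 0.47) and Cd96 at -0.76 (SD 0.11). Of 33 interferon response genes (median -0.20, SD 0.10), Ifi27l2a (-1.45, SD 0.14), Oas2 (-0.88, SD 0.17) and Ifit3 (-0.67, SD 0.03) were lower. Another 2 of the 33 went at least 1.5-fold opposite ways on the 2 arrays. Of 23 glucocorticoid-induced and stress genes (median -0.13, arrays -0.08 and -0.22), the chaperone gene Hsp90aa1 was higher at 1.03 (SD 0.60) and Txnip lower at -0.77 (SD 0.08). Of 24 glycolysis and hypoxia genes (median 0.03, arrays -0.0012 and 0.05, percentile 81.7), Tpi1 was higher at 0.82 (SD 0.21). Of 28 nuclear receptor and clock genes (median -0.01, arrays -0.05 and 0.04), Cry1 (-0.77, SD 0.15) and Arntl (-0.65, SD 0.07), both of the circadian clock, were lower, and the nuclear receptor gene Rora did not pass the rule (-0.18, SD 0.01). Cd8a, a coreceptor gene, lay on opposite sides of 0 on the arrays (-0.08, SD 0.39).

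Markers of other cell types moved in both directions beside these thymocyte groups. Of 36 markers of macrophages and dendritic cells (median -0.15, SD 0.06), H2-Eb1 (-0.82, SD 0.03), Ctss (-0.82, SD 0.07), Cd74 (-0.75, SD 0.15) and H2-DMb1 (-0.66, SD 0.04) were lower; all 4 act in antigen presentation by class II molecules. Of 23 B cell markers (median -0.14, SD 0.01), Jchain (-1.34, SD 0.26), Fcrla (-0.84, SD 0.07) and Cd79a (-0.68, SD 0.10) were lower. Of 23 thymic epithelium markers (median -0.17), Fezf2 (-1.30, SD 0.26), Krt5 (-0.98, SD 0.17) and Epcam (-0.69, SD 0.10) were lower. Of 34 fibroblast and endothelium markers (median -0.08, arrays -0.08 and -0.04), Postn was lower at -1.18 (SD 0.39). Of 21 NK and cytotoxic cell markers (median -0.07, arrays -0.11 and -0.08, percentile 1.00), Gzma was higher and Ccl5 lower at -1.01 (SD 0.48). Of 20 granulocyte and mast cell markers (median 0.11, SD 0.02), 4 neutrophil genes were higher, which were Ngp, S100a8 (1.22, SD 0.49), S100a9 (0.96, SD 0.19) and Camp (0.69). None of the 20 erythroid markers (median -0.02, arrays 0.0016 and -0.0093, percentile 28.5) or of the 11 sex-linked genes (median 0.01, arrays 0.05 and -0.09, percentile 60.4) passed the rule.

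In all, the medians of 15 of the 26 lists lay below and 5 above the central 95% of 10000 random lists of the same size. Of the 15, 7 came to lie within it on 1 of the arrays alone. These were the apoptosis (percentile 5.61), cytokine (12.9), fibroblast and endothelium (10.9) and NK (4.06) lists on the array with null in Cy3, the double positive (9.41) and glucocorticoid (3.96) lists on the array with null in Cy5, and the type 17 list on each (4.46 and 8.85). The file holds no intensities, so random lists could not be matched on expression. Their genes were drawn singly, so they do not allow for genes that vary together. The difference of the arrays divided by 2, which is dye and noise, also placed 3 lists outside. These were the double positive (percentile 100), mitosis (98.94) and ribosomal protein (100) lists. A place outside the random lists thus does not by itself mark a genotype effect.

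**Figure D3:**
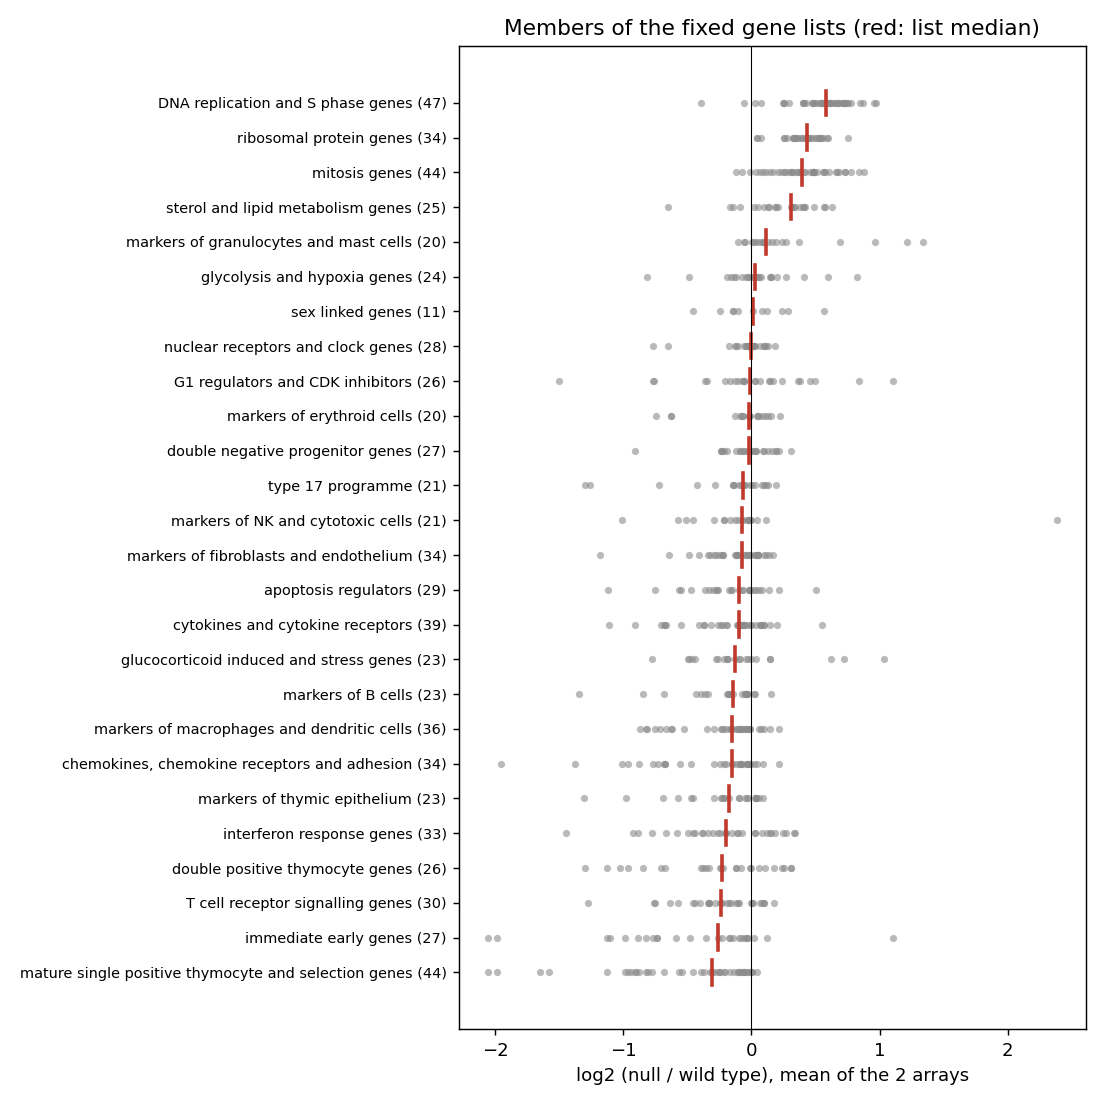
Log2 of null over wild type, the mean of both arrays, for each measured member of the 26 gene lists (grey points), with each list's median in red and the number of members in brackets. The replication list has the highest median at 0.58 and the list of mature single positive thymocyte and selection genes the lowest at -0.31.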

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

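All tests in this part were chosen after the results were seen, except for the bounds for the other histone genes. Those bounds were set before the genes were looked at. The comparison of the SD of these genes with their gap to the replication list replaced an earlier form after the value was seen. Each direction and each test of dye bias here rests on the second column being already turned, as inferred; if both columns were raw, values shared by the arrays would be the dye term, and the replication median would be 0.04.

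The 4159 features without a gene name entered no comparison. Of these, 8 were at least 1.5-fold higher and 25 at least 1.5-fold lower in the null pool on both arrays, a share of 0.793%. On simulated arrays, 0.797% of unchanged genes were called, but that noise came from named genes and had no preferred direction. The 2 shares are thus unlike and do not tell whether these calls are noise. A further 474 went at least 2-fold opposite ways on the 2 arrays, 471 of them lower on the array with null in Cy5. They recur at short steps of the feature numbers, with 459 of 473 steps of 8 or less.

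In the null pool, 7 of 47 replication genes, 2 of 44 mitosis genes and 3 of 6 measured histone H4 genes passed the rule as higher. Dye bias is argued against, on that reading, by the lowest of the 4 medians of the replication and mitosis lists per array, 0.34. The mitosis list did have a dye term, with a median of 0.06 (percentile 98.94), which is smaller than each of these medians. A rise of all replication-dependent histone transcripts was weighed with the 17 measured H1, H2A, H2B and H3 cluster genes. Their median of 0.11 lay under the bound of 0.3 and 0.47 below that of the replication list, with 1 of them above it. Their SD was 0.25, and the first form of the comparison, which set the SD against the bound of 0.3, did not decide. The gap to the replication list exceeded that SD, but this condition was added after the value was seen. It also rests on the array with null in Cy5, where their median was 0.03 and the gap 0.56. With null in Cy3 they were 0.29 and 0.21, a gap under the members' SD there of 0.37. Whether each of the 17 is made during replication in thymocytes was not examined. The test thus cannot decide, and a rise stays open, since 9 were above and 2 below 0 on both arrays. Their median lay at percentile 99.6 of random lists. A larger share of dividing cells in the null pool is a biological hypothesis that these pools cannot separate from a change within cells.

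The lists of markers of B cells, macrophages and dendritic cells, thymic epithelium, and fibroblasts and endothelium had medians below their random lists. So did the NK and cytotoxic cell list (-0.07, percentile 1.00), which was not weighed here, while the erythroid list (-0.02, percentile 28.5) did not. In the 4 lists named first, 11 of 116 members passed the rule as lower. The fibroblast and endothelium list, with 1 such member of 34, came to lie within its random lists on the array with null in Cy3 alone (percentile 10.9) and over genes with a small dye term (7.32). On the same reading, dye bias is argued against for the B cell, macrophage and dendritic cell, and thymic epithelium lists. In these, 3, 4 and 3 members were lower and none went opposite ways. In the fibroblast and endothelium list, 1 member was lower and 1 went opposite ways, so dye bias stays open there. A smaller share of all non-thymocyte cells was weighed with the granulocyte and mast cell list, which did not fall with the others. Its median was 0.11 (percentile 99.85), and of its 20 members, 12 lay above and 2 below 0 on both arrays. Without 4 neutrophil genes, the other 16 had a median of 0.09, with 8 above and 2 below 0 on both arrays. The bound was written after this list's value was seen, and the values are small, so the test cannot decide. The median of the full list lay 0.22 above that of the 116 members. The SD of that gap between arrays, 0.03, is technical and does not measure the spread over markers. A smaller share of single cell types, from genotype or from dissection, is also possible and was not tested.

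The neutrophil genes Ngp, Camp, S100a8 and S100a9 were higher in the null pool. Of the other 16 markers of the granulocyte and mast cell list, 50% were higher on both arrays. This is too few for the bound set for more neutrophils and too many to exclude it. The 16 include mast cell genes, such as Cpa3, which need not follow neutrophils, so the share cannot decide.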

How the results depend on the processing

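No paired analysis was possible because the 2 arrays hold the same pools and no test was run. Centring and the largest feature per gene left each count within 1.5 times and moved none of the 26 list medians or 76 named genes by over 1 SD. On 1 array alone, 381 to 482 genes were higher and 407 to 442 lower, counts that keep the dye bias of that array. A gene that passed the rule cannot change sign on 1 array, since the rule asks for the same direction on both. No list outside its random lists changed sign. However, 6 genes and 11 lists (array with null in Cy5) and 3 genes and 12 lists (the other) moved by over 1.5 times. Of the genes that passed the rule these were Rag1 (-0.75), Il7r (-0.59), Ccl5 (-0.67) and Ltb (-2.00) with null in Cy5, and Ltb (-0.61) and Hsp90aa1 (0.61) with null in Cy3. Other thresholds changed the counts by construction: 7 higher and 43 lower at 2-fold, 188 and 285 for 1.5-fold in the mean alone, and 158 and 275 beyond the 99th percentile of the dye term. Of the called genes, 64 and 176 had a dye term of at most 1/3 of the effect. Over genes with a dye term under 0.2 or of at most 1/3 of the effect, 7 list medians moved by over 1 SD, and the type 17 (percentile 2.65) and fibroblast lists (7.32) came within their random lists, while the double positive median was -0.12. On 1 array alone, 7 lists did, all of them below in the main setting. With the values read as log2, only 2 genes were higher and 4 lower, and 17 list medians moved by over 1 SD. The correlation of the arrays was 0.405 over genes at least 1.5-fold on either array. A dye term smoothed over intensity was not run, since no intensities are in the table. Signal over background, which limits small ratios, is unknown.

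With both columns read as raw Cy5 over Cy3, an alternative chosen after seeing the data, 16 genes were higher and 56 lower. None can be among the genes called above, since this reading asks for opposite signs in the columns and the main one for the same sign. For the same reason the 72 named genes that passed the rule could not pass here, and 0 of the 76 did. Then 3 lists lay outside their random lists, those of double positive, mitosis and ribosomal protein genes. Among lists outside their random lists and genes that passed the rule, signs turned for list medians (double positive thymocyte genes 0.15, mature single positive thymocyte and selection genes 0.0258, chemokines, chemokine receptors and adhesion 0.0041, glucocorticoid induced and stress genes 0.0471, immediate early genes 0.0357, markers of B cells 0.00302, markers of macrophages and dendritic cells 0.0282 and markers of thymic epithelium 0.0487) and for Gzma -0.078, H4c4 -0.385, H4c1 -0.186, H4c14 -0.174, Nme4 -0.0138, Mcm6 -0.0236, Cks1b -0.0603, Tpi1 -0.147 and Camp -0.000895, and for Glcci1 0.351, Lsp1 0.118, Cd69 0.0436, Egr1 0.00562, Nabp1 0.332, Ccl21c 0.143, Mr1 0.036, Ccl12 0.13, F13a1 0.293, Wfdc18 0.344, Bcl2a1b 0.0413, Fas 0.105, Spo11 0.262, Rag1 0.377, Il7r 0.318, Ptprc 0.0272, Cd52 0.221, Btg1 0.0604, Ccl20 0.173, Ifngr1 0.328, Jak1 0.0124, Cxcl10 0.331, Cd96 0.077, Ier5 0.0457, Jchain 0.182, Fcrla 0.0463, H2-Eb1 0.0246, Cd74 0.105, H2-DMb1 0.0318, Fezf2 0.186, Krt5 0.124 and Ccl5 0.338. If the second column was already turned, as inferred, these values are the dye term.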

Other observations

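The gene families in this part were chosen after single-gene values were seen. Their signs and medians rest on the second column being already turned, as inferred. With both columns read as raw, a gene with near-equal values on the arrays, such as Gimap6 (-1.09 and -1.16), would show no clear difference. All 7 measured GIMAP genes, GTPases of lymphocyte survival, lay below 0 on both arrays, with a median of -0.57 (SD 0.12), and Gimap3 (-0.82), Gimap4 (-1.65) and Gimap6 (-1.13) passed the rule. Granzyme genes did not move as a family: Gzma and Gzmc (0.78, SD 0.10) were higher and Gzmb stood at -0.57 (SD 0.03). The median of the 10 was 0.01 (-0.0095 with null in Cy5 and 0.04 with null in Cy3). Of 11 immunoglobulin segments, 4 were lower, among them Igkv6-20 (-1.06), Iglv1 (-0.97) and Igkv19-93 (-0.96), while Ighm stood at 0.15.

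Several other families had medians above 0, and in most of them many members differed in sign between the arrays. Of the 9 measured genes of the chaperonin CCT, which folds actin and tubulin, 8 lay above 0 on both arrays, with a median of 0.55 (SD 0.18), and Tcp1 passed the rule at 0.68. The 12 genes of Sm and U snRNP proteins, parts of the spliceosome, had a median of 0.51 (0.33 with null in Cy5 and 0.54 with null in Cy3). Of these, 10 lay above 0 on both arrays and 2 differed in sign. The 38 proteasome subunits had a median of 0.31 (0.16 with null in Cy5 and 0.34 with null in Cy3), 14 differed in sign between the arrays, and none passed the rule. The 76 mitochondrial ribosomal proteins had a median of 0.19 (0.12 with null in Cy5 and 0.23 with null in Cy3; 25 differed in sign), and the 34 NADH dehydrogenase subunits of the respiratory chain one of 0.26 (SD 0.02; 10 differed in sign). Nucleoporins had a median of 0.13 (SD 0.04). Genes taken as translation initiation factors by their symbol had one of 0.14 (0.06 with null in Cy5 and 0.21 with null in Cy3), and 16 of 43 differed in sign. They include regulators of initiation, such as Eif2ak1 and Eif4ebp1, and the pseudogene Eif2s3x-ps1, so the median is not that of the factors alone. Importins and exportins had a median of 0.11 (0.12 and 0.26), and 11 of 21 differed in sign. The family medians in this part, also those of the GIMAP, granzyme and immunoglobulin genes, were not recomputed with the second column read as raw. Whether they would keep their sign on that reading is thus not shown.

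Among the H4 genes, H4c1, H4c4 and H4c14 lay above 1.5 in log2, while H4c9 stood at 0.37, H4c11 at 0.03 and H4c8 at -0.02.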
